A study of Canis lupus familiaris with 21 samples.

How the data were processed

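RNA of MDCK-II cells, a line of dog kidney epithelial cells, was measured on 21 two-colour Agilent canine expression arrays. Per the labels, the Cy5 channel of each array held RNA of cells overexpressing 1 of 7 transcription factors, and the Cy3 channel held RNA of control cells with an empty vector. There were 3 arrays for each of E47, Snail1, Snail2, Twist1, Twist2, Zeb1 and Zeb2, called biological replicates in the labels. Clones were picked after drug selection, but the labels do not say whether the 3 arrays of a line came from separate clones or cultures, so p-values measure the spread between these arrays, part of which may be technical. No dye swap is named in the labels, and dye bias of a probe stays in each ratio against control. The labels' extraction protocol speaks instead of tumours and of a Cy3 pool made from the samples themselves. With a pool of equal parts of the samples, a probe's linear ratio would average 1 over the arrays apart from dye bias, and dye bias alike on all arrays would enter every line with a slope of 1. Over all tested probes of the value table, the log2 of the average ratio had a standard deviation of 1.07, above the 0.741 of the Zeb1 line's own log2 ratio. The slope of the lines on it ran from 0.339 for Zeb1 to 1.36 for Twist2. In 20 simulated pools it was 0.985 to 1.01, a value near 1 that their construction set, with dye bias dealt to probes at random. In the recorded arrays it ran from 0.29 for Zeb1 to 1.40 for Twist2. These values go against a pool of equal parts with dye bias alike on all arrays and unrelated to the lines' own changes. Pools of unequal parts were not tested. Cy3 is called control here, after the source and reference labels of that channel. Dye bias that differed between slides was not tested, and this check was chosen after seeing the data.

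Each scanner file holds, per the file headers, output of Agilent Feature Extraction 10.7.1.1 (version 10.0 per the submitters' processing notes). The intensity columns used, per the file headers, are the median pixel brightness of each spot and of its local background in both channels, with nothing subtracted, and the processed signals, in which the scanner software had subtracted background and normalised the dyes within the array. The deposited LogRatio column is the log10 ratio of processed Cy5 over processed Cy3 signal. A value table of the whole series holds 21 columns, 1 per sample. For the 15 that equal a scanner file, comparison showed the same deposited log10 ratio of Cy5 over Cy3. For the other 6, all of Snail1 among them, the same scale and direction were assumed. The median of every column was 0. Whether any centring was added to these columns is not given in the sources used here, nor is their further processing.

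The sample of each file was taken from the deposit's record, and the sample of each column from its name. The 2 sources conflict. Over the probes that passed the filter, 15 columns equalled the log10 ratios of a scanner file within 1e-04 at 97.7% to 97.8% of the probes, and in each case that file is recorded for another sample. Over all 42034 probes, without the filter, the first such pair had 904 unequal probes, and 904 of these share a transcript name with another probe. Another column lay close to a file (r = 0.965 across probes, with 0.934 for the next column) without equalling it, and the other 5 columns equalled none. The design fixed before the data were examined took the scanner files, with their recorded samples, as the first source and the value table as the alternative. Both are therefore given throughout, as arrays recorded for a line and as value-table columns of that line. They differ in processing as well as in samples, since the columns that equal a file hold ratios of the processed signals.

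Intensities were corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50, on the median signals because the files hold no mean signals, and normalised within each array by loess. The 1417 control spots and spots with outlier flags had weight 0 in the loess and were then left out. Of 42034 probes, the 30183 that were well above background in either channel on at least 3 of the 21 arrays were tested. Value-table ratios were multiplied to the log2 scale and used for the same probes. Each probe is 1 spot with its own ID, so no spots were averaged. One limma fit over all 21 arrays gave 7 line means of log2(Cy5/Cy3) and a shared variance (lmFit, eBayes). A probe was called where the Benjamini-Hochberg adjusted p was under 0.05 and the absolute log2 value was at least 1. A line mean was tested against 0, with control RNA present only as the common Cy3 channel, which leaves out the control's own spread. Differences between lines, in which the shared control and dye bias alike on all arrays cancel but dye bias that differs between slides does not, were tested for 4 pairs and by a moderated F test over all 7 lines.

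Names of genes were to come from the files' transcript names, through a RefSeq table for the dog. That table named 711 of the 42034 probes, for 694 genes. Of the 7 factors only SNAI2 had a named probe, and of the 924 genes in the lists fixed beforehand 92 had one. A check of these names against the measurements failed, as the report gives in full, so no value is attached to a gene name. The tests of 29 gene lists, the check for markers of other cell types, the gene-by-gene naming rule and the averaging of probes per gene were not run. The naming rule fixed beforehand took each factor's own transcript, the most changed genes per line, a fixed set of epithelial, mesenchymal and chromatin genes, leading members of each list, the most different genes per pair and over the lines, and the most changed genes among those called the same way in all 7 lines. Only this last part was applied, to spots, and the text names the 2 with the highest and the 2 with the lowest mean ratio by their listed ID and place on the grid.

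The procedure was tested on simulated ratios with each probe's own spread and 200 of 30183 probes changed in the Snail1 line. For that line against control it called 82% of probes changed 3-fold and 98% of those changed 6-fold, with 8 false calls. For the difference between Snail1 and Snail2 lines it called 69% and 88% at these folds, with 7 false calls, and the F test over lines called 63% and 83%, with 11. With the value table's spread the corresponding shares were 79% and 96% against control with 9 false calls, 54% and 86% between the lines with 7, and 45% and 82% for the F test with 4. The simulated ratios held no deviation of the control, so the false calls against control leave that error out.

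Alternatives covered the background correction, the normalisation within and between arrays, the filter on dim probes, the source of values, the slide as a block, the replicate number as a block, the variance model, array weights, the thresholds and leaving out each array. The slide and the position on it come from the file headers, and 7 slides of up to 4 arrays each were used. Replicate numbers in the labels were not used to pair the arrays, except in the alternative with the replicate number as a block.

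In the line channel between 34.4% and 67.2% of probes were well above background per array, and in the control channel between 50.5% and 67.4%. Up to 1.57% of probes per array carried outlier flags. The number of arrays limits the precision: the median standard error of a line's mean log2 ratio was 0.20 in the recorded arrays and 0.248 in the value table.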

Results

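Gene expression was compared between MDCK-II cells, an epithelial line from dog kidney, that overexpressed 1 of 7 transcription factors, and control cells carrying an empty vector. E47, Snail1, Snail2, Twist1, Twist2, Zeb1 and Zeb2 are known as regulators of the epithelial to mesenchymal transition, in which epithelial cells lose their junctions and become motile. The series title names Zeb1 and Snail1 and their part in transcriptional and epigenetic regulation during that transition. Each line had 3 arrays, 21 in all, with the line's RNA in Cy5 and, by the channel's source label, the control's in Cy3. Each array held 42034 probes, of which 30183 passed the filter on signal and 20102 of these were well above background on all 21 arrays. In the line channel the share of probes well above background ran from 34.4% in the third array of Twist2 to 67.2% in the third of Zeb2. In the control channel it ran from 50.5% in the first array of Zeb2 to 67.4%, again in the third array of Zeb2. At most 430 probes per array were saturated in the line channel and 124 in the control channel. Control-channel intensities of any 2 arrays correlated across probes with a median r of 0.96 and a lowest r of 0.82. Probes are not independent replicates, here and in every correlation across probes given for these arrays.

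The arrays recorded for 1 line often resembled arrays of another line more than each other. Over the recorded samples, the log2 ratios of 2 arrays of the same line correlated across probes with a mean r of 0.612, against 0.549 for arrays of different lines. This difference was not larger than regrouping the arrays gives (one-sided permutation test, 100000 resamples, p = 0.09), and only 4 of the 21 arrays had an array of their own line as nearest neighbour. The lowest r within a line was -0.221, between arrays recorded for Snail1, and the highest between lines was 0.973. Over all probes, without the filter, the lowest r between any 2 arrays was -0.22.

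The value-table columns of a line resembled each other more. Their mean r was 0.818 within lines and 0.536 between lines, with a lowest within-line r of 0.475. The permutation p was 1e-05, the smallest that 100000 resamples can give. Regrouping ignored slides, and files that equal the columns place those of Snail2, and those of Zeb1, on a single slide each. Likeness within a slide may therefore add to likeness within a line. Of the 21 columns, 19 had a column of their own line as nearest neighbour. The 2 exceptions were the first Twist1 column, with a mean r of 0.717 to its own line, 0.758 to the Twist2 columns and 0.724 to the Zeb2 columns, of which 1 was its nearest at 0.812, and the first Zeb2 column, with 0.484 to its own line and 0.567 to the Snail1 columns.

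**Figure D1:**
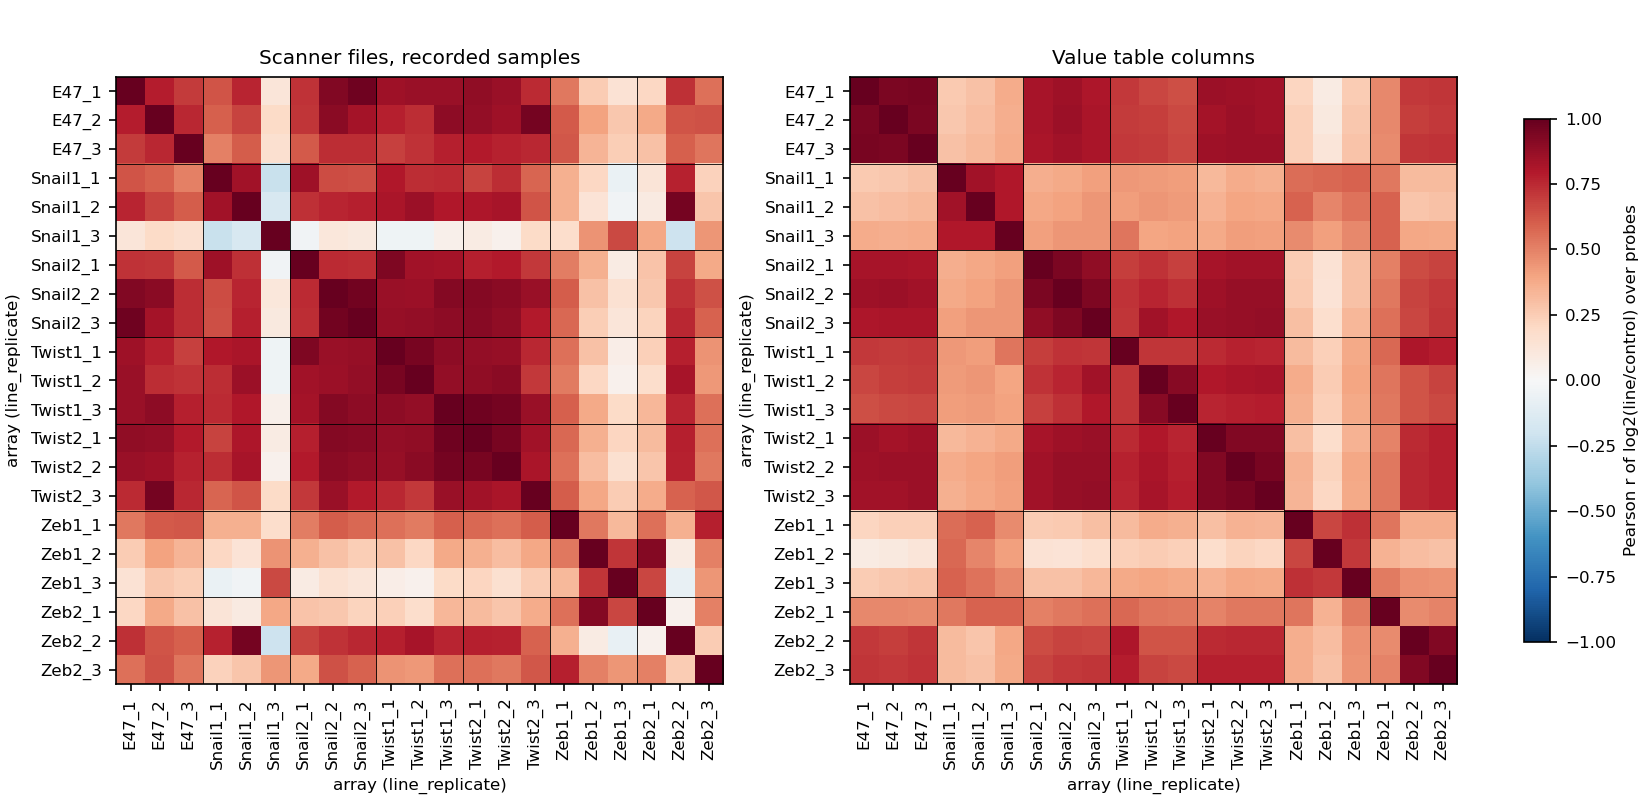
Pearson r of log2(line/control) over probes between every pair of the 21 arrays, for scanner files with their recorded samples and for value-table columns. Both axes list the arrays by line and replicate. Mean r within lines was 0.612 in the recorded arrays and 0.818 in the value-table columns.

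In part, both sources hold the same measurements under different samples. Of the 21 columns, 15 equalled the log10 ratios of a scanner file within 1e-04 at 97.7% or more of the probes. None of the 15 (0) belonged to the sample recorded for that file, 6 belonged to the same line and 9 to another line. On every slide the arrays are numbered from 1 to 4 along its length. For 15 of these 15 columns, the line was the one recorded at the mirrored position of the same slide, counted from the opposite end, and for 12 the sample was too. Random exchange of the lines over all 15 columns gave at most 11 (permutation test, 100000 resamples, p = 1e-05, the smallest they can give). This exchange ignored the slides, so its p partly measures that lines lie on different slides. Exchange within slides was not run, and the mirrored rule was chosen after seeing these data. The files recorded for Snail1 (3 arrays) and for the other two Zeb2 arrays, 5 files in all, had no file at their mirrored position, and their highest r with any column was 0.799. Taking only the 15 equal arrays, the lowest r within a line was 0.328 under the recorded samples and 0.665 under the value table's samples.

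Probes could not be tied to genes. Among probes listed under a common transcript name there were 893 pairs, and their mean intensities correlated with r = -0.0631 (95% interval -0.128 to 0.00247, two-sided permutation p = 0.059, 100000 resamples). Random pairs gave r between -0.11 and 0.108 in 1000 draws. For 440 pairs whose ratios moved between arrays, the median r of their ratios over arrays was 0.0365, against -0.0095 for random pairs. In 21 of 21 files the design number of the grid, which supplies probe IDs and names, differed from the design number of the slide. Control spots lay where the grid puts them: 100% of bright corner spots were well above background, against 3.66% of dark corners and 2.61% of negative controls. Each result is therefore given for probes as spots on the array, with no gene name.

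**Figure D2:**
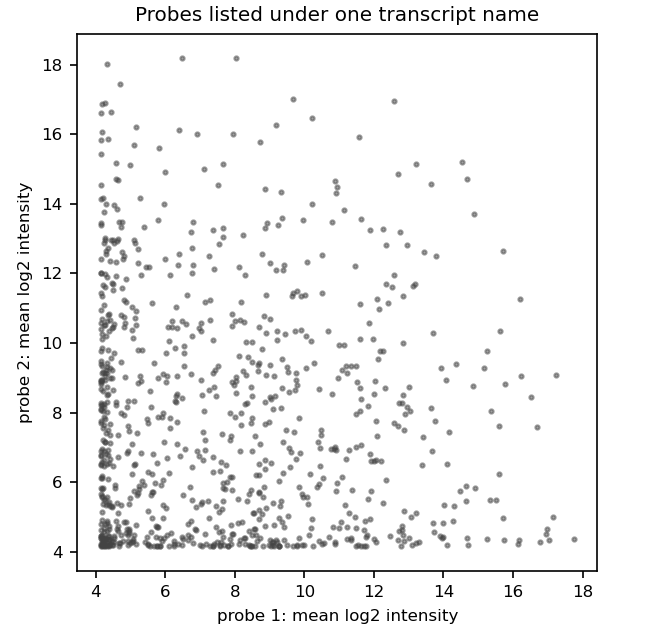
Mean log2 intensity of the first probe against the second for the 893 pairs of probes listed under a common transcript name, 1 point per pair. Pairs measuring the same transcript would lie along a rising line, and r was -0.0631.

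Which transcripts changed with each factor was asked by testing each line's ratio against 0. With the settings fixed beforehand, E47, Snail2, Twist1 and Twist2 had the most probes called, in both directions and in near equal numbers. Some alternatives changed this order of lines. In the arrays recorded for E47, 2297 probes were higher and 2305 lower than control. In those recorded for Snail2, 2507 were higher and 2590 lower. For Twist1 the counts were 2630 higher and 2997 lower, and for Twist2 they were 2638 and 2924. Changes over 4-fold numbered 860 for E47, 993 for Snail2, 1107 for Twist1 and 1171 for Twist2. The standard deviation of the mean log2 ratio over probes was 0.795, 0.83, 0.868 and 0.873 in the same order, against a median standard error of 0.20 (n = 3 arrays per line).

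The value-table columns of these lines gave more calls. E47 had 7829 probes higher and 7215 lower, Snail2 had 6916 and 6943, Twist1 had 4811 and 6341, and Twist2 had 7063 and 7548. Of the probes called in the recorded arrays, 3992 of 4602 for E47, 4805 of 5097 for Snail2, 4027 of 5627 for Twist1 and 5385 of 5562 for Twist2 were called with the same sign in the value table. Independent lists would share 1146.8, 1170.2, 1048.8 and 1348.5 in this order. For Snail2 and Twist2, part of the arrays are the same measurements under the same line in both sources, so these overlaps are not independent agreement. The number of recorded calls depended on single arrays. It was 2550 for E47 without its first array, 939 and 1185 for Snail2 without its second or the third, 1972 for Twist1 without its second, and 2794 and 2355 for Twist2 without its first or second. Centring each array on its median gave E47 1054 higher and 1238 lower, Snail2 3228 and 568, Twist1 4972 and 596, and Twist2 1096 and 2398. Scaling the ratios between arrays gave E47 112 higher and 29 lower, Snail2 1280 and 1021, Twist1 369 and 414, and Twist2 102 and 14. With that scaling E47 and Twist2 had fewer calls than Zeb1. With the slide as a random block, Snail2 had 2838 calls. The scanner software's processed signals raised the counts to 9819 for E47, 13280 for Snail2, 13890 for Twist1 and 12274 for Twist2. The Twist1 count then exceeded the value table's 11152. Those of E47, Snail2 and Twist2 stayed below the value table's 15044, 13859 and 14611.

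Fewer probes were called in the other three lines. In the arrays recorded for Snail1, 165 probes were higher and 469 lower. In those recorded for Zeb1, 54 were higher and 16 lower, and for Zeb2, 72 were higher and 18 lower. Changes over 4-fold numbered 92, 12 and 5. The standard deviation of the mean log2 ratio over probes was 0.544 for Snail1, 0.322 for Zeb1 and 0.489 for Zeb2. Whether a line changed fewer probes than another was not tested. The value-table columns gave many more calls here too, again with other processing as well as other samples. Snail1 had 1896 probes higher and 1395 lower, Zeb1 had 1556 and 1538, and Zeb2 had 4436 and 4716. Of the probes called in the recorded arrays, 83 of 634 for Snail1, 65 of 70 for Zeb1 and 69 of 90 for Zeb2 were called with the same sign in the value table. The overlap of independent lists would be 32 for Snail1, 3.6 for Zeb1 and 13.4 for Zeb2. For Zeb1, part of the arrays are the same measurements under the same line in both sources.

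These smaller counts rested on single arrays. Snail1 had 10, 1 and 3603 calls without its first, second or the third array, 421 without the second array of Zeb1 and 1144 without the second of Zeb2. Zeb1 had 0, 11 and 0 calls without its own arrays in turn. It had 44 without the second array of Snail2, 39 and 42 without the first or second of Twist1, and 42 and 40 without the first or second of Twist2. Zeb2 had 1181, 48 and 6 without its own arrays in turn and 260 without the third array of Snail1. Median centring left 1 probe higher and 0 lower for Snail1, 28 and 0 for Zeb1, and 14 and 1 for Zeb2. Scaling between arrays gave 7 higher and 12 lower for Snail1, 217 and 178 for Zeb1, and 28 and 59 for Zeb2. With the slide as a random block the calls numbered 137, 7 and 37. Processed signals raised them to 7148, 1037 and 1516, and no background correction to 3607, 649 and 1231. With processed signals the recorded Snail1 count thus exceeded the value table's 3291, while Zeb1 and Zeb2 stayed below its 3094 and 9152. Array weights gave 3044 for Snail1 and 311 for Zeb1, while a variance model with trend and robust fitting left 2, 1 and 1. The weights of the Snail1 arrays in turn were 5.7, 0.254 and 0.216, and those of Zeb1 1.46, 8.36 and 0.807. Weighted results for these lines thus rest mainly on 1 array each.

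**Figure D3:**
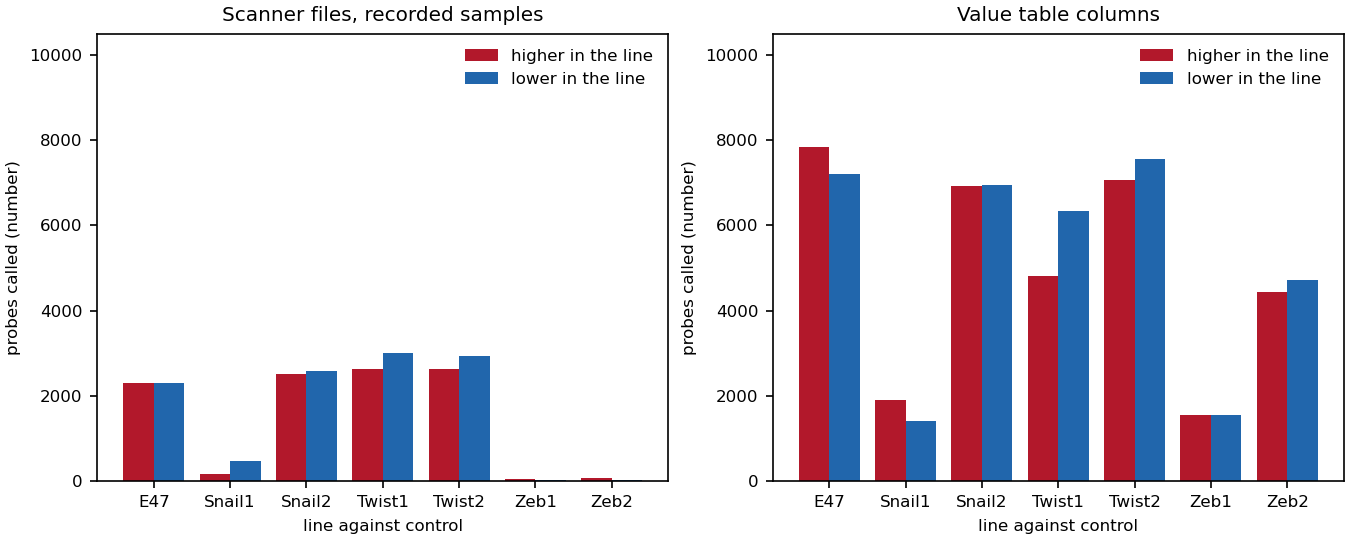
Number of probes called higher or lower than control in each line, for recorded arrays and value-table columns, with adjusted limma p under 0.05 and at least a 2-fold change. The recorded arrays give from 70 calls for Zeb1 to 5627 for Twist1, and the value-table columns from 3094 for Zeb1 to 15044 for E47. Recorded arrays and columns differ in processing as well as in samples.

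Lines were compared with each other through their correlations and shared calls. In the value table, the mean r between columns of different lines lay between 0.683 and 0.856 among E47, Snail2, Twist1 and Twist2. Columns of Snail1 or Zeb1 correlated with those of these lines at 0.2 to 0.434, and with each other at 0.524. E47 and Twist2 shared 5723 probes called higher and 6030 called lower, where independent lists would share 1832 and 1804.3. Snail1 and Zeb1 shared 847 higher and 667 lower, where independent lists would share 97.7 and 71.1, and 47 probes were called in opposite directions. In the recorded arrays the highest mean r between lines was 0.876, for Snail2 and Twist1, and Snail1 correlated with Zeb1 at 0.249. There E47 and Twist2 shared 1927 higher and 1995 lower, where independent lists would share 200.8 and 223.3. Snail1 and Zeb1 shared 10 higher and 5 lower, where independent lists would share 0.3 and 0.2.

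All ratios share the control RNA, which makes lines correlate with no effect at all. Simulated unchanged lines against a single control, in which the control deviates as much as an array of a line does, gave a mean r of 0.75 between line means over 21 pairs of lines in 20 simulations. This simulated r was the same for both sources, because the assumed control deviation and the number of arrays per line fix it. The observed mean r was 0.757 in the recorded arrays and 0.606 in the value table. Comparing these values with 0.75 therefore cannot show how much of the correlation comes from the shared control. The mean covariance of log2 ratios was 0.37 in the recorded arrays against a simulated 0.235, a difference of 0.135. For the value table it was 1.02 against 0.273, a difference of 0.749. Unchanged lines so simulated had a mean of 1490 calls each with the recorded arrays' spread and 2070 with the value table's. The former exceeds the recorded calls of Snail1, Zeb1 and Zeb2, so a control that deviated this much could alone give such counts. The simulated covariances and calls rest on the assumed control deviation, which was set from the spread within lines. In the recorded arrays this spread may include differences between lines, since the recorded samples conflict with those of the value table. The control could not be split into parts, so part of the excess over independent lists may come from the shared control.

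In differences between lines the shared control and dye bias alike on all arrays cancel, while dye bias that differs between slides stays. Snail1 and Snail2 differed at 11 probes in the recorded arrays, 1 higher and 10 lower in Snail1. The value-table columns differed at 11862 probes, 5986 higher and 5876 lower in Snail1. The recorded count was 285 without the first array of Snail2 and 1 without either of its others. It was 3, 1 and 3 without the arrays of Snail1 in turn, 17 without the third array of E47 and 19 without the third of Zeb2. No slide held arrays of both lines. With the slide as a random block 1 probe was called, and median centring or scaling between arrays left 0. Array weights, which rest mainly on the first Snail1 array, raised the count to 3688, processed signals to 231 and no background correction to 186.

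Twist1 and Twist2 differed at 0 probes in the recorded arrays by limma. At an unadjusted limma p under 0.05 there were 538 probes, where 1509 would be so by chance, and the smallest adjusted p was 0.87. With a count under chance, these p-values may run too high, so the lack of calls does not show that the lines are alike. Without the third array of Twist1 there were 19 calls, and with array weights 1. With slide as a fixed block, or within the slide that held both lines, the count was 0, but that slide held 1 Twist1 array against 3 of Twist2, and the lone array is assumed to vary like the others. The value-table columns differed at 3142 probes, 1252 higher and 1890 lower in Twist1. This count was 1755 without the first Twist2 column and 2018 without the third Twist1 column.

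Zeb1 and Zeb2 differed at 1 probe, higher in Zeb1, in the recorded arrays. The count was 0 after median centring, 0 after scaling, 0 with processed signals and 0 with array weights. It was also 0 with slide as a fixed block and within the slide that held both lines, but that slide held 1 Zeb2 array against 3 of Zeb1, so these fits are weak and assume that the lone array varies like the others. It was 3 without the second array of Zeb1, and 11, 0 and 5 without the arrays of Zeb2 in turn. At an unadjusted limma p under 0.05 there were 294 probes, where 1509 would be so by chance. Since the count lies under chance, these p-values may run too high, and the single call does not show that the lines are alike. Among value-table columns 6327 probes differed, 3229 higher and 3098 lower in Zeb1. That count was 10202, 3832 and 3187 without the Zeb2 columns in turn and 3994 without the second Zeb1 column.

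Zeb1 and Snail1, the factors in the series title, differed at 0 probes in the recorded arrays by limma. There were 1547 probes at an unadjusted limma p under 0.05, where 1509 would be so by chance, and the smallest adjusted p was 0.81. Without the third array of Snail1 the count was 3, without the second of Zeb1 it was 2 and without the second of Zeb2 it was 1. Array weights, which rest mainly on the first Snail1 and the second Zeb1 array, raised it to 2806, and processed signals gave 1. Among value-table columns 1081 probes differed, 515 higher and 566 lower in Zeb1. No slide held recorded arrays of both.

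Over all 7 lines together, the moderated F test called 74 probes in the recorded arrays, 0.245% of those tested. It called 22859, or 75.7%, in the value table. The recorded count was 472 without the first array of Snail2, 322 without the second of Zeb2, 178 without the third of Snail1 and 140 without the third of E47. It lay between 25 and 43 when any 1 of 11 other arrays was left out, namely the second or the third of Snail2, the first of Snail1, the first or second of Twist1, the first or second of Twist2, any of Zeb1 or the first of Zeb2. Median centring and scaling between arrays each left 0 calls, and the slide as a random block left 4. Array weights raised the count to 9257, processed signals to 1327 and no background correction to 517.

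Probes called the same way in all 7 lines were few in the recorded arrays, with 7 higher and 4 lower. The value table gave 444 higher and 269 lower. Independent lists would share 4.3e-08 probes in the recorded arrays and 0.064 in the value table. Simulated unchanged lines with a shared control gave a mean of 197 and at most 223 in the recorded arrays, more than observed. For the value table they gave a mean of 273 and at most 327, fewer than observed. These lines had a mean of 1490 and 2070 calls each, set by the assumed control deviation. The first comparison was fixed by list size, since Zeb1 had 70 recorded calls. The second also depends on list size, so neither decides whether sharing exceeds that of the control. Without single arrays the recorded count was 3, 0 and 25 for those of Snail1 in turn, 0, 2 and 0 for those of Zeb1 in turn, and 1 for the third of Zeb2. Median centring left 1 higher and 0 lower. Processed signals raised the count to 420, no background correction to 195 and array weights to 21.

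The most raised and most lowered of these 11 probes had the same sign in 21 of 21 arrays and were well above background in both channels on all of them. They were picked as extremes among probes called the same way in all 7 lines, which made a shared sign close to certain. Dye bias of a probe or the control's own deviation would also give 1 sign in every line. The spot at row 315 and column 75, listed as A_11_P0000017900, had a mean log2 ratio of 2.11 over the lines (SD 0.577, n = 7 lines), from 1.28 to 2.83, with a largest adjusted p of 0.028. The spot at row 376 and column 31, listed as A_11_P00000780, had 1.72 (SD 0.565, n = 7 lines), from 1.04 to 2.50, with a largest adjusted p of 0.046. The spot at row 505 and column 68, listed as A_11_P0000023407, had -3.33 (SD 0.931, n = 7 lines), from -4.55 to -2.22, with a largest adjusted p of 0.013. The spot at row 268 and column 14, listed as A_11_P0000031951, had -2.75 (SD 0.733, n = 7 lines), from -3.90 to -1.96, with a largest adjusted p of 0.038. Their means in the value table were 2.39, 1.67, -3.72 and -2.81 in the same order, and they were called in 7, 5, 7 and 7 lines. Most value-table columns equal these same arrays, so those means are not independent. Over 36 alternatives the spots were called in all lines in 24, 10, 26 and 17, with 0 changes of sign.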

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

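The tests weighed in this part, and what the counts over regroupings would show, were all chosen or written only after the results were seen. Among results that differed between lines, the recorded arrays gave 11 probes for Snail1 against Snail2, 1 for Zeb1 against Zeb2 and 74 over all 7 lines.

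The count of 74 was reached in 4 of 100 regroupings of the 21 arrays, the real one included, a share under 0.05. The regroupings ignored the slides that arrays of a line share, the count was 4 with the slide as a random block and 0 after median centring, and arrays of a line were not more alike than regrouping gives (permutation p = 0.09), so the count is not shown to follow the recorded lines. The highest other regrouping gave 2790 probes, many times the real count, which points to a structure of the samples other than the recorded lines. With the value table's samples 22859 probes differed, 1 of 100 regroupings gave as many, and the highest other gave 139. For pairs of lines, 3 arrays against 3 make 10 splits, too few for a share under 0.05. Snail1 against Snail2 gave 11, reached in 2 of the 10 splits, and the highest other was 1979, for the first Snail2 array with the first and the third of Snail1 against the rest. Zeb1 against Zeb2 gave 1, reached in 3 splits, with a highest other of 1. Twist1 against Twist2 gave 0, which every split reaches by definition, with a highest other of 7. Zeb1 against Snail1 also gave 0, so its 10 splits decide nothing. The highest other was 753, for the first and second Snail1 arrays with the first of Zeb1 against the rest, and the median of the others was 0. The value-table columns gave 11862 for Snail1 against Snail2 with a highest other of 1, 3142 for Twist1 against Twist2 with 41, 6327 for Zeb1 against Zeb2 with 1217, and 1081 for Zeb1 against Snail1 with 0, and 1 of 10 splits, the real one, gave as many in each pair.

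The conflict between recorded samples and value columns may come from positions numbered from opposite ends of the slide, since 15 of 15 equal columns carried the line recorded at the mirrored position. A few swapped labels are excluded, because 0 of these columns equalled the file of their own sample. Clones of a line that differ from each other are excluded as the whole cause, since the lowest r within a line, over the same arrays, rose from 0.328 to 0.665 under the value table's samples. Over these 15 arrays the mean r within a line also rose, from 0.756 under the recorded samples to 0.869, which argues against the recorded samples there. For the other files the right source stays open. The mirrored rule cannot be checked on the 5 files with no file at their mirrored position. Snail1 files 1 and 2 had an r of 0.0374 and 0.0694 with their own sample's column, against 0.799 and 0.795 with an E47 column. Snail1 file 3 had 0.483, against 0.685 with another Snail1 column. Zeb2 files 2 and 3 had 0.634 and 0.443, against 0.779 with an E47 column and 0.728 with a Snail1 column. Snail1 files 1 and 2 thus did not resemble their own columns, which does not show which source is right.

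Probes listed under a common transcript name did not measure alike, and names taken from another array design are a candidate explanation, with r = -0.0631 and a design number that differed in 21 of 21 files. A grid shifted by up to 8 positions or turned is excluded, since the highest r over 1156 placements was 0.13. Weak probes on an otherwise right map are excluded by the upper bound of r, 0.00247. No biological explanation was tested.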

How the results depend on the processing

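The scanner arrays under the value table's samples and the value table with columns left out were chosen after seeing the data, and the other alternatives before. Counts are of called probes, and the cause of a change was not tested except where fewer arrays or a stricter threshold make it. A normexp offset of 16 kept 13 of 13 counts within 1.5 times. Of the 4 named spots 0 reversed over 36 alternatives, with mean log2 ratios of 2.05 to 3.49, 1.66 to 2.57, -4.80 to -2.51 and -4.76 to -1.90 in the report's order, and calls in all lines in 24, 10, 26 and 17 of these. Their choice as extremes of these arrays made a kept sign likely.

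The value table gave 15044 for E47, 3291 for Snail1, 13859 for Snail2, 11152 for Twist1, 14611 for Twist2, 3094 for Zeb1, 9152 for Zeb2, 11862 for Snail1 against Snail2, 3142 for Twist1 against Twist2, 6327 for Zeb1 against Zeb2, 1081 for Zeb1 against Snail1, 22859 over lines and 713 the same way in all. Without the first Twist1 and the first Zeb2 column these became 15075, 3500, 13926, 11795, 14652, 3300, 12418, 12489, 5554, 10715, 1680, 25695 and 695. The 15 scanner arrays under the value table's samples gave 341 for Zeb1, 456 for Zeb2 (1 array, assumed to vary like the other lines), 694 for Twist1 against Twist2 and 44 for Zeb1 against Zeb2. Under their recorded samples the same arrays gave 183, 1, 4 and 0.

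No background correction gave 3607 for Snail1, 7798 for Snail2, 649 for Zeb1, 1231 for Zeb2, 186 for Snail1 against Snail2, 517 over lines and 195 the same way in all. The scanner software's processed signals gave 9819 for E47, 7148 for Snail1, 13280 for Snail2, 13890 for Twist1, 12274 for Twist2, 1037 for Zeb1, 1516 for Zeb2, 231 for Snail1 against Snail2, 0 for Zeb1 against Zeb2, 1 for Zeb1 against Snail1, 1327 over lines and 420 the same way in all. Median centring gave 2292 for E47, 1 for Snail1, 3494 for Twist2, 28 for Zeb1, 15 for Zeb2, 0 for Snail1 against Snail2, 0 for Zeb1 against Zeb2, 0 over lines and 1 the same way in all. Scaling between arrays gave 141 for E47, 19 for Snail1, 2301 for Snail2, 783 for Twist1, 116 for Twist2, 395 for Zeb1, 0 for Snail1 against Snail2, 0 for Zeb1 against Zeb2, 0 over lines and 0 the same way in all.

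No filter on dim probes gave 390 for Snail1, 44 for Zeb1 and 45 over lines. Probes well above background on all arrays gave 960 for Snail1, 164 for Zeb2 and 0 for Zeb1 against Zeb2. The slide as a random block (correlation 0.156) gave 137 for Snail1, 2838 for Snail2, 7 for Zeb1, 37 for Zeb2, 1 for Snail1 against Snail2, 4 over lines and 4 the same way in all. As a fixed block, or within a shared slide, it gave 0 for Zeb1 against Zeb2, where the shared slide holds 1 Zeb2 array against 3 of Zeb1, which shows little. The 6 arrays of both lines alone gave 0 for Snail1 against Snail2 and 0 for Zeb1 against Zeb2. Variances with trend and robust fitting gave 2 for Snail1, 1 for Zeb1, 1 for Zeb2, 3 for Snail1 against Snail2, 19 over lines and 0 the same way in all. Array weights gave 3044 for Snail1, 311 for Zeb1, 3688 for Snail1 against Snail2, 1 for Twist1 against Twist2, 0 for Zeb1 against Zeb2, 2806 for Zeb1 against Snail1, 9257 over lines and 21 the same way in all. The array weights ran from 0.124 for the second Zeb2 array to 8.36 for the second of Zeb1. With no minimum fold there were 8899 for E47, 9113 for Snail2, 9281 for Twist1, 10115 for Twist2 and 23 the same way in all. Tested against a 1.5-fold change, there were 749 for E47, 0 for Snail1, 895 for Snail2, 1285 for Twist1, 1642 for Twist2, 0 for Zeb1, 1 for Zeb2, 1 for Snail1 against Snail2 and 0 the same way in all.

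Leaving out 1 array at a time gave 2550 to 4984 for E47, 1 to 3603 for Snail1, 939 to 6648 for Snail2, 1972 to 5903 for Twist1, 2355 to 6406 for Twist2, 0 to 101 for Zeb1, 6 to 1181 for Zeb2, 1 to 285 for Snail1 against Snail2, 0 to 19 for Twist1 against Twist2, 0 to 11 for Zeb1 against Zeb2, 0 to 3 for Zeb1 against Snail1, 25 to 472 over lines and 0 to 25 the same way in all.

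Same-numbered arrays of different lines deviated with a mean r of 0.0894 (-0.516 to 0.913), over 0.1 in 31 of 63 pairs. These deviations were taken under the recorded samples, which conflict with the value table's, so they cannot show whether the numbers pair the arrays. The replicate block gave 1033 for Snail1, 144 for Zeb2 and 160 over lines, and moved no other count by over 1.5 times. Tests of gene lists and counts per gene were not run, as probes have no names that hold, and so were not their alternatives. Slide as a fixed block was not run over lines, for Snail1 against Snail2 or for Zeb1 against Snail1, since shared slides do not join these lines, and neither was a fit within a slide for these pairs. Signal over background limits the probes tested to 30183 of 42034.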

Other observations

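The tests in this part were all chosen only after the result was seen. In the value table, columns of Snail1 and Zeb1 stood apart from those of E47, Snail2, Twist1 and Twist2. Smaller responses drowned in noise were weighed by correcting each r for the spread within lines. After this, the highest r of Snail1 or Zeb1 with these lines was 0.543, below the lowest among the others, 0.795. Snail1 with Zeb1 reached 0.693. The Zeb1 columns share a slide, and likeness within a slide may raise r within a line and so lower the corrected r. The values argue against noise as the whole cause only if such likeness is small, which was not tested. For Zeb1, the values argue against a slide effect alike on both dyes as the whole cause. Control-channel intensities of the slide that held its columns correlated with those of slides 1 to 3 at a mean r of 0.963 (0.952 to 0.971 by array), against 0.98 among those slides. Line-channel intensities did so at 0.842 (0.817 to 0.866), against 0.948. Since the control channel fell too, a slide effect on both dyes that adds to the pattern is not excluded. A batch effect on Cy5 alone, the unknown slide of the Snail1 columns and a biological difference between the factors, which was not tested, stay open and could each account for the pattern.

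Some probes of the recorded arrays, with the filter not applied, were well above background in 1 channel on all 3 arrays of a line and in the other channel on 0. They numbered 172 in the line channel and 482 in the control channel for E47, 179 and 118 for Snail1, 701 and 681 for Snail2, 1008 and 502 for Twist1, 240 and 1102 for Twist2, 517 and 83 for Zeb1, and 74 and 5 for Zeb2. The third array of Twist2 had the lowest share of probes well above background in the line channel, 34.4%.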
